A study of Homo sapiens with 2 samples.

How the data were processed

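Chromatin from H1299, a human non-small cell lung cancer cell line, was immunoprecipitated with an antibody against histone H3 lactylated at lysine 18 (H3K18la) and sequenced (ChIP-seq). The series has 2 libraries, 1 immunoprecipitated and 1 input, so that each group holds 1 library. Only the peak list of the immunoprecipitated library was analysed here. The series' own design text speaks of an IgG group where the sample labels speak of input, and which of these served as the control of the peak calls could not be settled from the labels. The names of the peaks in the list begin with NC, which the labels do not explain, so that its assignment to the anti-H3K18la library rests on the labels alone. There were no replicates, no p-values are given, and no interval below covers the spread between libraries. The binomial intervals cover counting error only.

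Per the labels, the submitters' processing notes name bcl2fastq 2.17, cutadapt 1.18 and Trimmomatic 0.38 for read preparation, Bowtie2 2.3.4.1 for alignment to hg38, Picard, MACS2 (both 2.1.2 and 2.1.0 are listed) for peak calling and ChIPseeker for annotation. The deposited list is in the broad peak format of MACS2 and has no header. Its deposited fold enrichment of each peak is a ratio of the immunoprecipitated library to the caller's local background. The deposited significance of each peak is given as -log10 p (neg_log10_p) and as -log10 q. The deposited score equalled the whole part of 10 times -log10 q in 99.98% of peaks. The caller's settings and threshold are not stated in the labels, and the largest q in the list was 0.0472. The depth of either library is unknown, so a gene without a listed peak is described as having no peak in this list, not as lacking the mark. How reads matching several near-identical gene copies were placed was not examined. Values and missing peaks at such copies therefore carry a further limit. Fold enrichment of a broad peak is an average over its length, so that a wide peak with a strong centre has a lower value than a narrow peak of the same height.

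Peaks were compared with a table of NCBI RefSeq genes for GRCh38, which gives each gene's start and end on its chromosome but no strand, exons or transcripts, so that exonic, intronic and untranslated positions could not be assigned. The planned promoter window around the 5′ end was therefore replaced by windows of 1000 bp either side of both ends of each protein-coding gene. A peak that overlapped such a window by 1 bp or more was counted as lying at a gene end, and where several did so the peak of highest fold was taken as the gene's peak. Some of these peaks lie at the 3′ end of the gene named or belong to a neighbour, and any other gene at whose end the same peak lies is named beside it. Of 59679 placed gene entries, 718 whose coordinates belong to alternate or unlocalised sequences were left out, which left 19866 protein-coding genes on chromosomes 1 to 22, X and Y.

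The share of peaks and of genes was given with the exact (Clopper-Pearson) 95% binomial interval. Peaks were also placed at random 100 times on the same chromosome with the same widths, without masking of unsequenced stretches. For 34 gene lists fixed before the data were examined, the number of members with a peak at an end was ranked among 10000 random lists of the same size drawn from all protein-coding genes. A list is described as above or below the random lists where it passed their 97.5th or fell under their 2.5th percentile. This ranking describes 1 library and is no test across replicates. Ribosomal, mitochondrial ribosomal, NADH dehydrogenase, proteasome, nucleoporin, histone, HOX, zinc finger, olfactory receptor, keratin-associated, beta-defensin and cancer-testis lists were drawn by symbol, the other lists by hand.

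Genes were named by a rule fixed before the data were examined. It took the 20 genes with the highest fold at an end, the 10 genes with the widest peak there, up to 4 members with the highest fold and up to 4 without a peak from each list, and POM121. It also took every member of the glycolysis, lactate, histone writer, immune checkpoint and MYC network lists, and the 5 peaks of highest fold over 50000 bp from any protein-coding gene end. It covered 287 genes, of which the text names a part. POM121C, GTF2IRD2, PVT1 and the genes named only as neighbours of a peak were chosen after their values were seen.

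For the closing observations, the control background behind each peak was solved from its fold enrichment and -log10 p under the Poisson model of MACS2, in the scaled read units of the caller. The procedures were tested on simulated data. All of 5000 genes with a planted peak were found, and the overlap equalled a brute-force count in 500 of 500 genes. Of lists of 20 genes drawn without enrichment, 3.8% fell outside the range, and 97.6% of lists planted at 95% were placed above it. These tests check the code only. Planted peaks were centred on gene ends, and unenriched lists came from the same distribution as the random lists. They cannot show how genes that share a peak affect the ranking. The solved background of averaged peaks was a median of 1.07 times the true value. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

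Alternatives were a -log10 q of at least 2 or 5, the upper part of the peaks by fold (above the median), joining of peaks with gaps under 3000 bp, windows of 3000 bp or of 2000 bp outward and 500 bp inward of a gene end, the peak's midpoint or 50% coverage as the overlap rule, genes of every biotype, shuffling over the whole genome, and random lists matched on gene length. After the data were seen, a peak anywhere in the gene, genes with no other gene end within 5000 bp, and shuffling outside gene-free stretches over 1000000 bp were added.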

Results

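In H1299 cells, H3K18la was mapped by ChIP-seq to find where in the genome this histone mark lies. Lactylation is a modification of histone lysines derived from lactate, the end product of glycolysis. The list held 28695 broad peaks, which covered 44.6 Mb of chromosomes 1 to 22 and X. Peaks had a median width of 1250 bp (quartiles 711 and 1921) and ranged from 288 to 26015 bp. Their median fold enrichment over the local background was 4.36 (quartiles 3.50 and 5.83), the highest being 29.0. A fold of at least 10 was reached by 842 peaks, and 76 peaks were wider than 10000 bp.

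Peaks lay at the ends of protein-coding genes far more often than randomly placed peaks, and the strongest peaks most often. Of all peaks, 10720 (37.4%, 95% interval 36.8 to 37.9) lay within 1000 bp of a gene end, 9765 (34.0%) lay elsewhere inside a gene and 8210 (28.6%) lay between genes. Shuffled peaks reached a median of 4.72%, so that the observed number was 7.91 times the shuffled one (7.55 to 8.47 over the 100 sets). Direct overlap with a gene end was seen for 29.2% of peaks against 2.14% of shuffled peaks, and positions over 100000 bp from any gene end held 10.9% against 37.4%. Peaks at gene ends had a median fold of 5.46 and a median width of 1373 bp, compared with 3.88 and 1175 bp inside genes and 3.91 and 1111 bp between genes. The difference in median fold between gene-end peaks and all others was 1.57 (bootstrap 95% interval over peaks 1.51 to 1.63). The share at gene ends was 71.3% (69.6 to 72.9) in the decile of peaks with the highest fold and 13.0% (11.8 to 14.3) in the decile with the lowest.

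**Figure D1:**
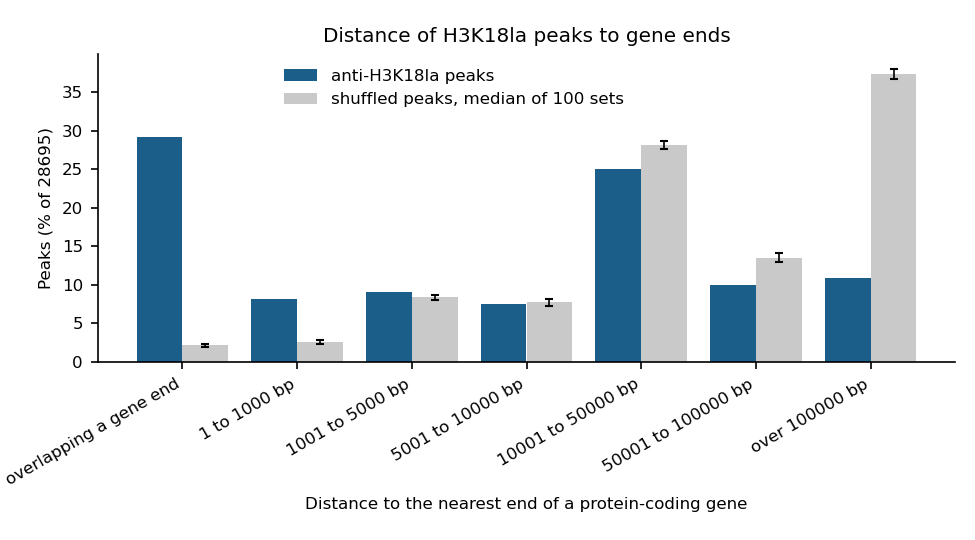
Share of the 28695 H3K18la peaks (%, vertical axis) in classes of distance to the nearest end of a protein-coding gene (horizontal axis), beside the median of 100 sets of peaks shuffled within chromosomes, with whiskers from the lowest to the highest set. The share overlapping a gene end was 29.2% against 2.14% of shuffled peaks, and the share over 100000 bp away was 10.9% against 37.4%.

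At least 1 peak lay at an end of 11744 of 19866 protein-coding genes (59.1%, 58.4 to 59.8). Among 7360 genes longer than 10000 bp with no other protein-coding gene end within 5000 bp, 53.2% (52.0 to 54.3) had a peak at 1 end only and 1.92% (1.61 to 2.26) at both. The share of genes of all biotypes with a peak at an end was 29.2%, and a peak anywhere in the gene or its flanks was found for 66.7% of protein-coding genes.

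The gene with the highest fold at an end was GTF2IRD2B (NCBI gene 389524), a general transcription factor II-I repeat gene, with a peak of 29.0-fold at 75092483 to 75093052 on chromosome 7. Its near-identical copy GTF2IRD2 had 7.77-fold, and whether reads were placed correctly between the copies was not tested. Next were the splicing factor gene SF1 (21.7-fold, chromosome 11, 64777823 to 64778676), the transcriptional repressor gene ZBTB18 (20.5-fold, chromosome 1), the small GTPase genes CDC42 (20.01-fold, chromosome 1) and RAB11B (19.1-fold, chromosome 19), and CUL3 (19.7-fold, chromosome 2). CUL3 encodes the cullin scaffold of the ubiquitin ligase that uses KEAP1 as its substrate receptor, and KEAP1 itself was among the 20 with 17.2-fold (chromosome 19, 10501620 to 10503702). Chromatin genes in this group were the nucleosome remodeller gene SMARCA1 (18.2-fold), the bromodomain genes BRD2 (17.97-fold) and BRPF3 (17.9-fold), the methyl-CpG binding protein gene MBD2 (17.2-fold) and the deacetylase gene HDAC7 (17.02-fold). HDAC7 had the highest significance of any peak in the list, with a -log10 q of 180.5 (chromosome 12, 47818454 to 47822211). At equal fold, a higher control background gives a higher significance. In the bin of HDAC7 (chromosome 12, 45 to 50 Mb) the background solved from the peaks had a median of 7.16. The 20 genes had 17 distinct peaks, since ZYX and FAM131B shared 1 peak (17.7-fold) and TNFRSF12A, HCFC1R1 and THOC6 shared another (17.3-fold).

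The widest peak at a gene end, 23895 bp, lay at ITGA3, the integrin alpha-3 gene (chromosome 17, 50043649 to 50067543, 7.80-fold). ZSWIM4 had 23204 bp, HOXB2 and HOXB3 shared a peak of 22412 bp, and UQCC1 had 19614 bp. The actin crosslinker gene ACTN4 had 14349 bp (5.72-fold) and the mRNA decay factor gene ZFP36L1 had 14019 bp (8.25-fold). ACTN4 lies in a stretch of chromosome 19 (30 to 45 Mb) and ZFP36L1 in a bin of chromosome 14 (65 to 70 Mb) in which the control background solved from the peaks was raised (medians 11.0 and 9.78, against 4.38 outside the chromosome 19 stretch). It was raised to a lesser degree in the chromosome 17 bins of ITGA3 (50 to 55 Mb, 7.62) and of HOXB2 and HOXB3 (45 to 50 Mb, 6.66). Under the rule that the peak's midpoint must lie in the window, these peaks no longer counted for ZSWIM4, HOXB2, HOXB3, UQCC1, ACTN4 and ZFP36L1, of which ZSWIM4 and UQCC1 had other peaks that did. Among the 20 genes of highest fold, HDAC7, FAM131B and THOC6 had no peak under that rule.

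Genes of glycolysis, the pathway that produces pyruvate and lactate from glucose, had peaks at their ends in 17 of 19 cases (89.5%, 66.9 to 98.7), against a median of 11 in random lists. The highest values were those of the phosphofructokinase gene PFKL (NCBI gene 5211, 15.8-fold, chromosome 21, 44299264 to 44301026, also at AIRE), GAPDH (NCBI gene 2597, 11.9-fold, chromosome 12, 6531559 to 6536637, also at NCAPD2) and the aldolase gene ALDOA (10.8-fold). The enolase gene ENO2 had 9.49-fold at its end of higher coordinate, in a peak that also lay at ATN1. Pyruvate kinase PKM had 8.22-fold, enolase ENO1 7.45-fold, the glucose transporter SLC2A1 5.94-fold, hexokinase HK2 4.92-fold and GPI 5.56-fold. GPI lies in the stretch of chromosome 19 with raised background. No peak lay at the ends of HK1 and ALDOC, although HK1 held 2 peaks inside the gene, of up to 6.03-fold. For 7 of the 17 genes the peak also lay at the end of another gene. With the midpoint rule ALDOA, ENO1, PFKFB4 and PKM had no peak and the count was 13 of 19, at percentile 87.7 of random lists, and the list was then no longer above them.

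Genes of lactate production and transport had peaks in 9 of 13 cases (69.2%, 38.6 to 90.9), within the range of random lists (median 8). The monocarboxylate exporter gene SLC16A3 had 12.3-fold (NCBI gene 9123, chromosome 17, 82211996 to 82220141), in a peak also at CCDC57, and BSG, whose product escorts monocarboxylate transporters to the membrane, had 9.84-fold. The lactate dehydrogenase genes LDHA and LDHB had 6.39-fold and 5.82-fold, and the pyruvate dehydrogenase kinase gene PDK1 had 6.79-fold. No peak lay at the ends of EMB, LDHC, PDK4 and SLC16A7, and EMB had 1 inside the gene (4.55-fold). Under the midpoint rule SLC16A3 and LDHD had no peak and the count was 7 of 13.

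Both lists of mitochondrial oxidation were above the random lists. Of the genes of the TCA cycle and pyruvate dehydrogenase, 19 of 21 had a peak (90.5%, 69.6 to 98.8, random median 12), with DLAT at 7.64-fold and SUCLG2 at 7.40-fold and none at SDHD and SUCLA2. Of the genes of NADH dehydrogenase subunits, 32 of 36 had a peak (88.9%, 73.9 to 96.9, random median 21), with NDUFB1 at 8.69-fold in a peak also at CPSF2, and none at NDUFA2, NDUFA3 and NDUFV1, among others. For 19 of these 32 genes the peak also lay at the end of another gene. Among peaks above the median fold, the counts were 13 of 21 and 22 of 36, at percentiles 93.5 and 97.1, and neither list was then above the random lists.

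**Figure D2:**
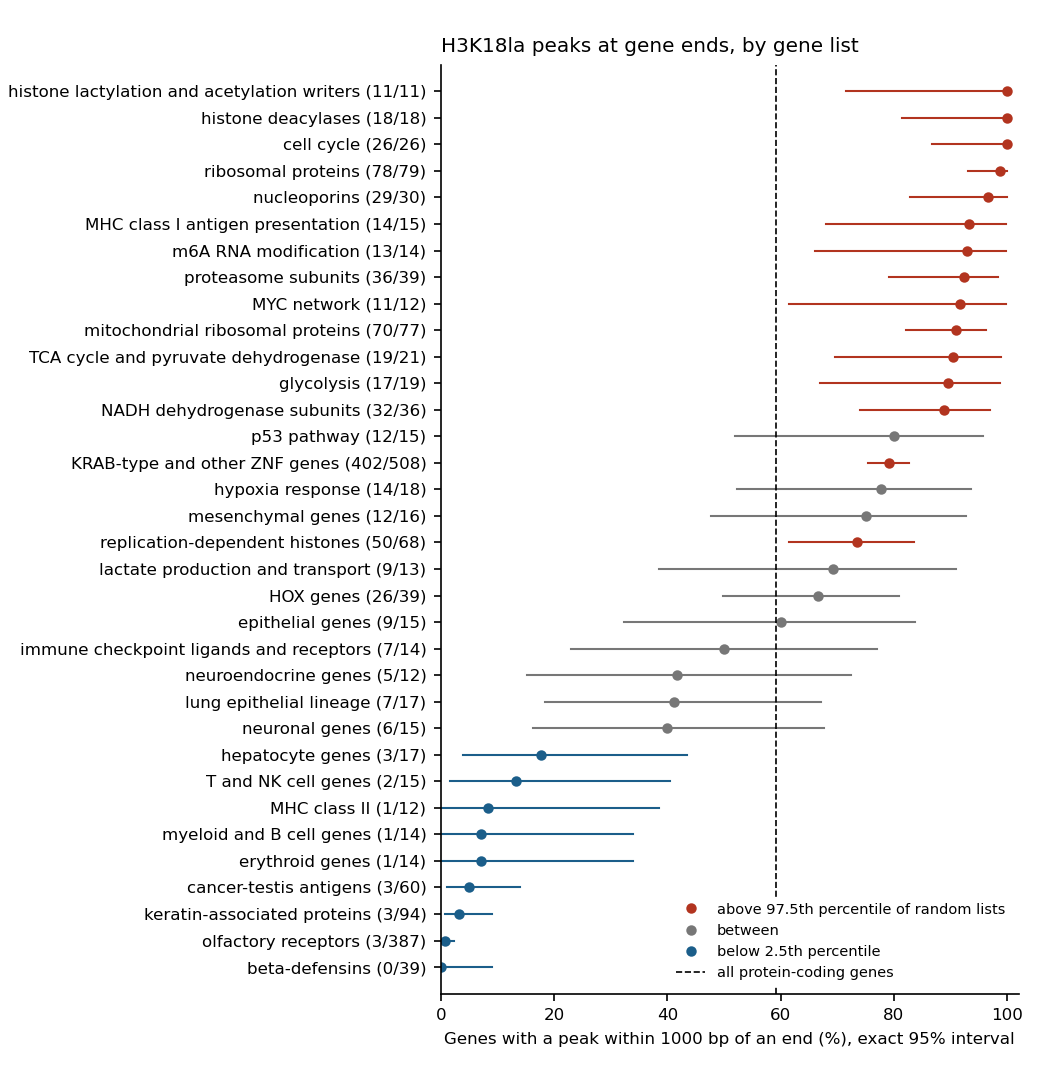
Share of genes (%, horizontal axis) with an H3K18la peak within 1000 bp of an end for each of the 34 gene lists (vertical axis, genes with a peak over all genes in brackets). Points are shares, bars are exact 95% intervals covering counting error only, colours give the position among random lists, and the dashed line marks the 59.1% of all protein-coding genes. Lists above the random lists run from histone writers at 11 of 11 to replication-dependent histones at 50 of 68. The p53 (12 of 15), hypoxia (14 of 18) and mesenchymal (12 of 16) lists lie to the right of these histones but within the range of random lists. Tissue-restricted families lie to the left, down to 0 of 39 beta-defensins.

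All 11 genes of histone lactylation and acetylation writers had a peak at an end (71.5 to 100%), against a random median of 7. CREBBP had 9.66-fold and EP300 6.31-fold, the paralogous acetyltransferases that can also use lactyl-CoA. KAT2B had 9.16-fold, KAT2A 8.25-fold, and the alanyl-tRNA synthetase genes AARS2 and AARS1 had 6.83-fold and 5.26-fold, the latter in a peak also at EXOSC6. The weakest were KAT5 (3.28-fold) and KAT8 (2.99-fold, also at BCKDK). With a -log10 q of at least 5, 9 of 11 remained listed, at percentile 97.1, and the list was no longer above the random lists. All 18 histone deacylase genes had a peak (81.5 to 100%, random median 11), led by HDAC7, HDAC2 (9.97-fold), HDAC5 (8.78-fold) and SIRT5 (8.40-fold).

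Nucleoporin genes, which encode the nuclear pore, had peaks in 29 of 30 cases (96.7%, 82.8 to 99.9, random median 18). The highest was AHCTF1 with 9.80-fold, and NUP35 had only a peak inside the gene (6.78-fold). POM121, a transmembrane nucleoporin (NCBI gene 9883), had a peak of 3.35-fold at its end of lower coordinate (chromosome 7, 72878127 to 72879931) with a -log10 q of 3.08, which was not listed at a -log10 q of at least 5. The near-identical gene POM121C had 6.33-fold, and the placing of reads between these copies was likewise not tested.

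Immune checkpoint genes had peaks in 7 of 14 cases (50%, 23.04 to 76.96), within the range of random lists (median 8). Among the ligands, the poliovirus receptor gene PVR had 8.77-fold, CD276 8.51-fold, PDCD1LG2 8.06-fold, NECTIN2 7.99-fold and CD47 5.43-fold. PVR and NECTIN2 lie in the stretch of chromosome 19 with raised background. CD274, which encodes PD-L1 (NCBI gene 29126), had a peak of 438 bp and 2.92-fold (chromosome 9, 5449848 to 5450285), which was not listed at a -log10 q of at least 5. No peak lay at VTCN1, LGALS9 or the lymphocyte receptor genes CTLA4, HAVCR2, LAG3, PDCD1 and TIGIT. The remaining marked gene, VSIR, had 5.54-fold.

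Genes of MHC class I antigen presentation had peaks in 14 of 15 cases (93.3%, 68.1 to 99.8, random median 9), and those of class II in 1 of 12 (8.33%, 0.211 to 38.5, random median 7). In class I, TAPBP had 8.22-fold and B2M 7.52-fold, in peaks also at RGL2 and PATL2, and HLA-C had none. The class I peak also lay at another gene's end in 7 of 14 genes, and with a -log10 q of at least 5 the count was 11 of 15, no longer above the random lists (percentile 94.2). The class II peak was at CIITA (4.54-fold), at the end it shares with DEXI.

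In the MYC network, 11 of 12 genes had a peak (91.7%, 61.5 to 99.8, random median 7), from MGA at 7.56-fold to MYCL at 2.66-fold, and MYCN had none. MYC itself (NCBI gene 4609) had a peak of 6612 bp and 4.72-fold (chromosome 8, 127734325 to 127740936). The neighbouring long noncoding gene PVT1 (127794524 to 128101256) overlapped 22 peaks from 2.46-fold to 7.39-fold, with a summed full width of 75474 bp. The first of these peaks began at 127793948, outside the gene. Under the midpoint rule MYC had another peak, of 3.13-fold, and the count was 10 of 12, at percentile 97.47, within the range of random lists, and it was also 10 of 12 by 50% coverage (percentile 96.5).

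**Figure D3:**
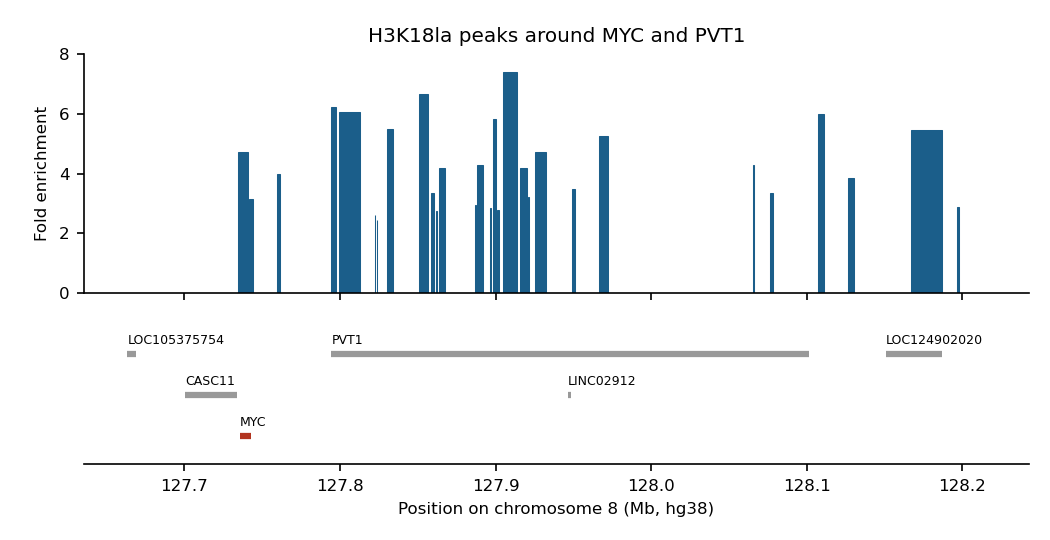
H3K18la peaks around MYC and PVT1 on chromosome 8 (horizontal axis, position in Mb, hg38), with the height of each box giving the fold enrichment of the peak and its width drawn to scale. Bars below are annotated genes, protein-coding in red and noncoding in grey. The peak at MYC reached 4.72-fold and the 22 peaks overlapping PVT1 reached 7.39-fold.

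The cell cycle, ribosomal and proteasome lists had peaks at most of their genes. All 26 cell cycle genes had a peak (86.8 to 100%, random median 15), among them E2F3 (13.4-fold, also at LOC124901482), the proliferation marker gene MKI67 (10.6-fold), MCM7 (9.91-fold, also at AP4M1) and the cyclin D1 gene CCND1 (9.13-fold). E2F3 had no peak under the midpoint rule, by which 24 of 26 counted. Ribosomal protein genes had peaks in 78 of 79 cases (98.7%, 93.1 to 99.97), with RPL10 at 8.88-fold. Mitochondrial ribosomal protein genes had peaks in 70 of 77 cases (90.9%, 82.2 to 96.3), led by MRPL2 (11.1-fold, also at CUL7), and 39 of those 70 peaks also lay at another gene. That list was no longer above the random lists among peaks above the median fold (percentile 97.03). Proteasome genes had peaks in 36 of 39 cases (92.3%, 79.1 to 98.4), with none at the ends of PSMA6, PSMA8 and PSMB11, although PSMA6 had 4.99-fold inside the gene. PSMA8 and PSMB11 are the testis and thymus forms of the complex.

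Genes of m6A RNA modification had peaks in 13 of 14 cases (92.9%, 66.1 to 99.8, random median 8), with YTHDF3 at 9.68-fold and none at the ends of FTO. The list was within the range of random lists at a -log10 q of at least 5 (10 of 14, percentile 92.2) and among peaks above the median fold (8 of 14, percentile 81.6). Replication-dependent histone genes, which lie in tight clusters, had peaks in 50 of 68 cases (73.5%, 61.4 to 83.5, random median 40), of which 40 were shared with another gene. Under the midpoint rule this list had 43 of 68 and was within the range. Zinc finger genes named ZNF had peaks in 402 of 508 cases (79.1%, 75.3 to 82.6, random median 300), with ZNF18 at 13.2-fold in a peak also at MAP2K4. Among genes with no other protein-coding gene end within 5000 bp, 5 of the 15 lists above the random lists were within their range, namely the TCA cycle (4 of 5), NADH dehydrogenase (4 of 5), MHC class I (6 of 7), the MYC network (6 of 7) and the histones (5 of 8). With a peak anywhere in the gene counted, the MYC network (11 of 12) and the histones (51 of 68) were within the range.

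Hypoxia response, p53 pathway and HOX genes lay within the range of random lists. The hypoxia genes had peaks in 14 of 18 cases (77.8%, 52.4 to 93.6), with HIF1A at 11.4-fold and VEGFA at 7.59-fold, and none at the ends of CA9, CA12, KDM3A and NDRG1, although KDM3A had 9.85-fold inside the gene. The p53 pathway genes had peaks in 12 of 15 cases (80%, 51.9 to 95.7), with MDM2 at 8.66-fold. BBC3, CDKN1A and FAS had peaks only inside the gene, of up to 11.5-fold, 6.32-fold and 5.38-fold. The p53 list was above the random lists with a window of 3000 bp (14 of 15), at a -log10 q of at least 5 (12 of 15, percentile 98.4) and under the midpoint rule (12 of 15, percentile 97.54). HOX genes, which pattern the body axis, had peaks in 26 of 39 cases (66.7%, 49.8 to 80.9), with HOXB9 at 10.2-fold, and were above the random lists with the 3000 bp window (32 of 39) and against random lists matched on gene length. With a peak anywhere in the gene counted, the hypoxia list (16 of 18) and the p53 list (15 of 15) were above the random lists, as was the hypoxia list among peaks above the median fold (13 of 18) and among genes with no other gene end nearby (10 of 13, percentile 97.96).

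Among lineage genes, epithelial and mesenchymal lists both lay within the range of random lists. Mesenchymal genes had peaks in 12 of 16 cases (75%, 47.6 to 92.7), with the receptor tyrosine kinase gene AXL at 8.94-fold over 12378 bp in the chromosome 19 stretch of raised background, ITGB1 at 8.49-fold, the transcription factor gene ZEB1 at 8.11-fold and the vimentin gene VIM at 8.09-fold. No peak lay at the ends of COL1A2, COL3A1, SNAI2 and ZEB2, and ZEB2 had 11.2-fold inside the gene. Under the midpoint rule 6 of 16 counted, without AXL, ITGB1 and ZEB1. Epithelial genes had peaks in 9 of 15 cases (60%, 32.3 to 83.7), among them KRT19 (7.58-fold, also at KRT15) and KRT7 (6.97-fold). The KRT19 peak (41519806 to 41523261) lay wholly outside that gene, below its end of lower coordinate (41523617), and KRT19 had no other peak. The KRT7 peak (52229315 to 52232314) likewise lay outside the gene, which begins at 52233243. No peak lay at the ends of the E-cadherin gene CDH1, EPCAM, ESRP1 and GRHL2, and CDH1 had 3.98-fold inside the gene. Under the midpoint rule 3 of 15 epithelial genes counted, at percentile 0.37, below the random lists. The lung epithelial lineage had peaks in 7 of 17 cases (41.2%, 18.4 to 67.1), of which the highest, at SFTPC (10.2-fold), was shared with BMP1. Neuroendocrine genes had peaks in 5 of 12 cases (41.7%, 15.2 to 72.3), with UCHL1 at 5.79-fold and none at CHGA or INSM1, and fell below the random lists under the midpoint rule and by 50% coverage (3 of 12 each). Neuronal genes had peaks in 6 of 15 cases (40%, 16.3 to 67.7), with DLG4 at 7.97-fold.

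Few genes of blood, liver and sensory lineages had a listed peak at an end. T and NK cell genes had peaks in 2 of 15 cases (13.3%, 1.66 to 40.5), at CD4 in a peak also at GPR162 (5.96-fold) and at CD8A (3.30-fold). Myeloid and B cell genes had 1 of 14 (7.14%, 0.181 to 33.9), at CD68 (6.51-fold) in a peak also at MPDU1. Hepatocyte genes had 3 of 17 (17.6%, 3.80 to 43.4), at TAT (5.09-fold), SERPINA1 (5.08-fold) and F2 (3.27-fold), and none at the albumin gene ALB. Erythroid genes had 1 of 14 (7.14%), at GATA1 (4.66-fold). Olfactory receptor genes had 3 of 387 (0.775%, 0.160 to 2.25), at OR2V2, OR1F1 and OR14A2, and keratin-associated protein genes had 3 of 94 (3.19%, 0.663 to 9.04), at KRTAP2-3, KRTAP21-3 and KRTAP4-9. Beta-defensin genes had 0 of 39. Cancer-testis antigen genes had 3 of 60 (5%, 1.04 to 13.9), at MAGEA4 (8.69-fold), MAGEA10 (7.57-fold, also at LOC100533997) and MAGEA1 (4.26-fold). These 3 genes lie on chromosome X, where 44.7% of protein-coding genes had a peak, and random lists were not matched on chromosome. All lists of this paragraph lay below the random lists, except that the erythroid list was within the range among genes with no other gene end nearby (1 of 7, percentile 4.5).

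Away from gene ends, 5997 peaks (20.9%) lay over 50000 bp from any protein-coding gene end, against 50.9% of shuffled peaks. The strongest of them lay on chromosome 9 at 129411979 to 129415027 (17.7-fold, 74922 bp from LOC124900275). The next was inside TAB2 on chromosome 6 at 149316682 to 149319196 (16.8-fold, 81066 bp from the end of SUMO4). The others were on chromosome 2 at 64864468 to 64865674, 122805 bp from the glutamate transporter family gene SLC1A4 (15.8-fold), inside MTA3 at 42567944 to 42569564 (15.2-fold), and inside PRDM11 on chromosome 11 at 45179856 to 45181769 (15.2-fold). Gene ends here are the outer limits of each gene. A peak inside a gene may therefore lie at the start of a shorter transcript, which was not tested.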

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

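Each test in this part was chosen after its pattern had been seen and before the test's own result was known, except the count at gaps between tRNA genes, which was added after the result for moved positions was known.

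Transfer RNA genes, which no comparison above describes on their own, carried peaks more often than other noncoding genes. Of 341 tRNA genes more than 3000 bp from any protein-coding gene end, 160 (46.9%, 95% interval 41.5 to 52.4) had a peak within 1000 bp, against 10.8% of long noncoding genes placed likewise; these were 116 distinct peaks. A broad active domain around the clusters is argued against where tRNA genes lie at least 5000 bp apart. Positions moved by 10000 bp carried a peak 0.118 times as often (25 of 450, 5.56%). Of 682 moved positions, 169 were left out near another tRNA gene and 63 near a protein-coding gene end. Midpoints of gaps of 5000 to 50000 bp inside the clusters had one in 9 of 124 cases (7.26%, 3.37 to 13.3). The tRNA genes beside them had one in 79 of 181 cases (43.6%, 36.3 to 51.2). Closer gaps were not examined, and the intervals treat genes that share a peak as independent. Reads shared among near-identical copies stay open, since genes with a sister of the same isodecoder had a peak 9.73 percentage points more often than genes without one (51.7% and 42.01%), with overlapping intervals. By chromosome, 8 of 9 had a peak on 17, 87 of 148 on 6, 20 of 74 on 1 and 0 of 21 on 7, and the share off chromosome 6 was 37.8%; no biological explanation was tested.

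The control background solved from the peaks, a quantity outside the main measurement, was raised on chromosome 19 from 30 to 45 Mb, with a median of 11.0 against 4.38 elsewhere, a ratio of 2.52. It stepped down from 11.9 at 45 to 46 Mb to 3.55 at 46 to 47 Mb, and the highest bin elsewhere, chromosome 14 from 65 to 70 Mb with 31 genes, had 9.78. Gene density is argued against, since the highest of 175 bins of 5 Mb with at least as many genes reached 0.71 times the lowest of these 3 bins. The next bin, 45 to 50 Mb, had 183 genes and 4.14. Averaging over wide or strong peaks is argued against as well, since narrow peaks of moderate fold kept a ratio of 2.68. That ratio rests on 26 such peaks in the 3 bins and 5662 elsewhere, and its spread was not measured. A candidate explanation is that H1299 cells carry more copies of this stretch, for which the peaks over 1000 bp from any gene end would have to be raised as well, and their ratio was 2.45; any other cause that raises the whole stretch would give this too, and copy number itself was not measured. The share of genes with a peak there was 66.5%, and the 5th percentile of fold was 2.44 against 2.90 elsewhere.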

How the results depend on the processing

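The last 3 alternatives named at the end of this part were chosen after the data were seen. In every alternative run that bears on them, peaks stayed enriched at gene ends over shuffled peaks and stronger there than elsewhere. The 28695 peaks fell to 18155 at a -log10 q of at least 5 and to 14347 above the median fold. The share of peaks at gene ends (37.4%) was 38.9% at a -log10 q of at least 2, 50.6% at 5, 54.4% above the median fold, 41.5% with peaks joined, 42.2% with a window of 3000 bp, 34.1% by midpoint, 35.4% by 50% coverage and 46.1% with all biotypes. The share of genes with a peak (59.1%) was 52.4% at a -log10 q of at least 5, 44.98% above the median fold, 62.4% with 3000 bp, 54.8% by midpoint, 56.9% by coverage and 29.2% with all biotypes. The fold over shuffled peaks (7.91) was 9.44 at a -log10 q of at least 5, 9.97 above the median fold, 4.58 with 3000 bp, 7.01 with 2000 bp outward and 500 bp inward, 12.2 by midpoint, 11.2 by coverage, 4.21 with all biotypes and 9.12 with shuffling over the whole genome. The difference in median fold (1.57) was 1.49 and 0.943 at a -log10 q of at least 2 and 5, 0.826 above the median fold, 1.39 with 3000 bp, 1.47 by midpoint and 1.44 with all biotypes. Fewer peaks at stricter thresholds and overlap rules give fewer marked genes by construction. The higher gene-end share at stricter thresholds goes with its range from 13.0% to 71.3% across fold deciles. Windows of 3000 bp and of all biotypes contain the main windows. The shares of peaks at gene ends could thus only rise there, as could the share of genes with 3000 bp. The cause of the other shifts was not tested. Lists above the random lists numbered 11 to 17 over the alternatives (15 in the main setting) and lists below them 8 to 11 (9). The fold of 39 of the 287 named genes changed under the midpoint rule, of 21 with 3000 bp, of 20 by coverage, of 16 above the median fold, of 12 at a -log10 q of at least 5, of 7 each with the outward window and with joining, and of 0 at a -log10 q of at least 2. Of the added alternatives, a peak anywhere in the gene gave 66.7% of genes, genes with no other gene end nearby gave 47.7%, and shuffling outside gene-free stretches gave 7.54. Start sites of single transcripts, promoter CpG content and CpG-matched lists were not run, because no strand, transcripts or sequence were at hand. Without known depth, and with 1 library, weak peaks such as that of CD274 are at the limit of what the list can show.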

Other observations

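The groupings and the test in this part were chosen after the data were seen, the test before its own result was known.

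Peaks joined across gaps of up to 12000 bp formed 19336 domains, of which 13923 were single peaks and 438 held at least 5. The domain with the most covered sequence lay over EXT1, which encodes a heparan sulfate polymerase, with 20 peaks covering 59490 bp on chromosome 8 from 117908463 to 118036078. The TGF-beta signal transducer gene SMAD3 followed, with 17 peaks covering 54344 bp and a highest fold of 9.09. Domains over SUSD1 (48875 bp), the long noncoding genes MIR100HG (47405 bp) and LINC-PINT (40126 bp), the stretch with MALAT1 (35390 bp) and the ephrin receptor gene EPHA2 (34217 bp, up to 12.6-fold) were among the next.

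Protein-coding genes grouped by the stem of their symbol gave 133 families of at least 15 genes, of which 47 lay above and 40 below the random lists. Near complete were the Integrator subunits (INTS, 16 of 16), the Mediator subunits (MED, 29 of 30), the TRAPP complex (TRAPPC, 16 of 17) and the VPS genes of endosomal sorting (32 of 35). Kallikrein (KLK, 0 of 15), late cornified envelope (LCE, 0 of 19), PRAMEF (0 of 22) and SPDYE (0 of 19) genes had none. Whether missing peaks in families of similar genes reflect the placing of reads was not tested. Chemokines named CCL had 1 of 26, UGT enzymes 1 of 22 and cytochromes P450 (CYP) 10 of 56. Of pseudogenes away from protein-coding ends 2.20% had a peak, and of microRNA genes 6.47%.

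Of 556 genes of the T cell, myeloid, hepatocyte, neuronal, erythroid, olfactory and keratin-associated lists, 19 had a peak at an end. That such peaks may belong to the promoter of a neighbour was tested by the share that also lay at another gene's end. It was 15.8% (3 of 19, 3.38 to 39.6) against 32.9% of all genes with a peak. A share at or below the latter had been set beforehand as counting against the explanation. With 19 genes, however, the interval includes 32.9%, and neighbours over 1000 bp from the peak were not counted. The explanation therefore stays open. The 3 were CD4, CD68 and GRIN1. Of the other 16, DLG4 and OR2V2 had the highest folds, 7.97 and 7.71. The OR2V2 peak (181160182 to 181160685) lay outside the gene, beyond its end at 181159285.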
